A study of Mus musculus with 8 samples.

How the data were processed

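The samples were bone marrow HSCs of wild-type C57B6/J mice, transduced with random DNA barcodes, transplanted into lethally irradiated mice and sorted by surface phenotype 20 weeks later, per the labels. Extraction and library construction followed the 10x Genomics single cell 3' v2 protocol, per the labels' protocols, although the overlap of cell barcodes between replicates leaves the kit version in doubt. The series has 4 DNA barcode libraries and 4 transcriptome libraries, each kind numbered as replicates 1 to 4. The transcriptome libraries are not analysed here, so no gene expression enters any result. The submitters' processing notes name Cell Ranger, without a version, and the mouse build mm10.

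For each DNA barcode library the authors deposited a text table with 1 line per cell. It gives the cell barcode of 16 bases, the DNA barcode of 21 bases or N, and a category c1 to c4 or N under the header Cluster, per the file headers and values. No read or UMI count, expression value or coordinate stands beside them, so no count model was used and sequencing depth is unknown. The depth of a result is therefore its number of cells, 2141 to 4718 barcoded cells per replicate. How DNA barcodes were read, filtered and given to cells, whether similar barcodes were merged, how doublets were treated, and how the categories were made are not given in the sources used here. Each of these steps can change the values: a filter on weakly supported barcodes would remove small clones, a sequence error left in would add them, and a droplet with cells of different clones would be listed under a single barcode. Every DNA barcode had 1 category in all its cells of a replicate, so the category was used as a label of the clone.

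A clone was defined as 1 DNA barcode in 1 replicate, seen in at least 1 cell. Of the barcodes, nearly all start with the bases GTG, and the other 18 positions vary. For each replicate the number of cells and clones, the share of the largest clone, the inverse Simpson index (effective number of clones, with the SE from 1000 bootstrap draws over cells), Shannon evenness, the share of clones seen in 1 cell and the Chao1 estimate were computed, then their mean and SD over the 4 replicates. Shares have 95% Clopper-Pearson intervals, which cover counting error only. Equal clone sizes were tested with a chi-square against 100000 multinomial draws in which each clone had at least 1 cell. Shared barcodes were counted over the 6 pairs of replicates, beside the number expected if each of the 18 variable positions were drawn at random with the observed base frequencies. The expectation was also computed among barcodes with the same number of T. By the naming rule, the 3 barcodes with the most cells in each replicate were named, and the 5 with the most cells among those found in more than 1 replicate. The clone measures, the equal-size test, the count of shared barcodes and the naming rule were fixed before the data were examined, and the expectations from base frequencies were added later in place of one with all sequences equally frequent, which gave 1.23e-06 matches.

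Two-sided permutation tests with 100000 draws compared clone size between labels. For each of the 6 pairs of labels, the mean log2 number of cells per clone was subtracted within each replicate and averaged over replicates, with labels permuted among the clones of those labels within a replicate. The overall test used Kruskal-Wallis H summed over replicates, and the spread of labels over replicates was tested with a chi-square and labels permuted over all clones. The pairs of labels, the overall tests of labels and the share of cells in c3 or c4 clones were added after the clone sizes per label had been seen. A test planned for cells with a state of their own was not run, because the category is fixed per clone, and a test of a number per cell was not run, because the tables hold none. Nothing in the labels says that the replicates came from separate animals, so an SD over replicates measures the spread between these libraries, part of which may be technical. Of 475 distinct barcodes 6 were in more than 1 replicate, which argues against the libraries being repeat samples of the same pool of cells.

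The tests by label were checked on simulated data with the real numbers of clones, in 200 simulations with 999 draws each. The multinomial test was checked in as many simulations of an invented library, whose numbers of clones and cells were not those of a replicate. With no simulated difference in size among the 468 labelled clones, the overall test called 7.5% of simulations and the c3 against c1 test 3%. With a simulated 2-fold difference these were 70% and 59.5%, and with a 4-fold difference 100% and 99.5%. With equal clone sizes simulated the multinomial test called 3%, and with labels shuffled over replicates the chi-square test called 3.5%.

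The alternatives tried were merging barcodes up to 1 or up to 2 bases apart, requiring 2 or 3 cells per clone, thinning each replicate to 2141 barcoded cells, leaving out the largest clone or clones, leaving out barcodes close to a larger clone or with a larger copy in another replicate, unlogged sizes or ranks, and leaving out each replicate in turn. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.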

Results

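Haematopoietic stem cells (HSCs) are the bone marrow cells that renew all blood lineages and refill the blood of an irradiated recipient. Here HSCs of wild-type C57B6/J mice had received random DNA barcodes by transduction before they were transplanted into lethally irradiated mice. A barcode is copied to all descendants of the transduced cell, so cells with 1 barcode are counted here as 1 clone. This equals the number of transduced cells only if each took up 1 barcode of its own, which was not tested. Cells with the surface phenotype of HSCs were sorted from the recipients' bone marrow 20 weeks after transplantation and processed on a droplet single-cell platform. The design has 4 DNA barcode libraries, named replicates 1 to 4, and 4 transcriptome libraries whose values are not analysed here. The labels give no second condition, so the 4 replicates form 1 group, and they do not say whether the replicates came from separate mice. The question addressed was how many transduced clones made up the HSC fraction at this time and how evenly they shared it.

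The barcode tables listed 3193, 2199, 4126 and 4893 cells for replicates 1 to 4, which is 14411 cells in all. A DNA barcode was given for 2479, 2141, 3374 and 4718 of them. The barcoded share was 77.6% in replicate 1 (95% Clopper-Pearson interval 76.2% to 79.1%) and 81.8% in replicate 3 (80.6% to 82.9%). It was 97.4% in replicate 2 (96.6% to 98.0%) and 96.4% in replicate 4 (95.9% to 96.9%). The mean was 88.3% ± 10.1 (SD, n = 4), so the replicates differed in this share by more than counting error. Each barcoded cell was listed with a single DNA barcode, so the share of cells with several barcodes is 0 by the layout of the tables. A clone missed in a replicate could hold up to 0.121%, 0.140%, 0.0889% and 0.0636% of the barcoded cells of replicates 1 to 4, from 3 counts of the total. These intervals and limits cover counting error only.

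The HSC fraction held between 88 and 176 barcoded clones per replicate, and a few of them made up much of its barcoded cells. Replicates 1 to 4 had 176, 92, 88 and 125 clones, a mean of 120.25 ± 40.7 (SD, n = 4). The largest clone held 12.8% of the barcoded cells in replicate 1 (11.5% to 14.2%), 28.9% in replicate 2 (27.0% to 30.8%), 19.7% in replicate 3 (18.4% to 21.1%) and 8.35% in replicate 4 (7.58% to 9.18%). The mean of the largest share was 17.4% ± 8.94 (SD, n = 4). The 10 largest clones together held 44.8%, 60.8%, 72.3% and 56.3% of the barcoded cells. The 13, 7, 4 and 8 largest clones were enough to reach 50% of the cells of replicates 1 to 4. The median clone had only 4, 4, 7 and 7 cells.

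**Figure D1:**
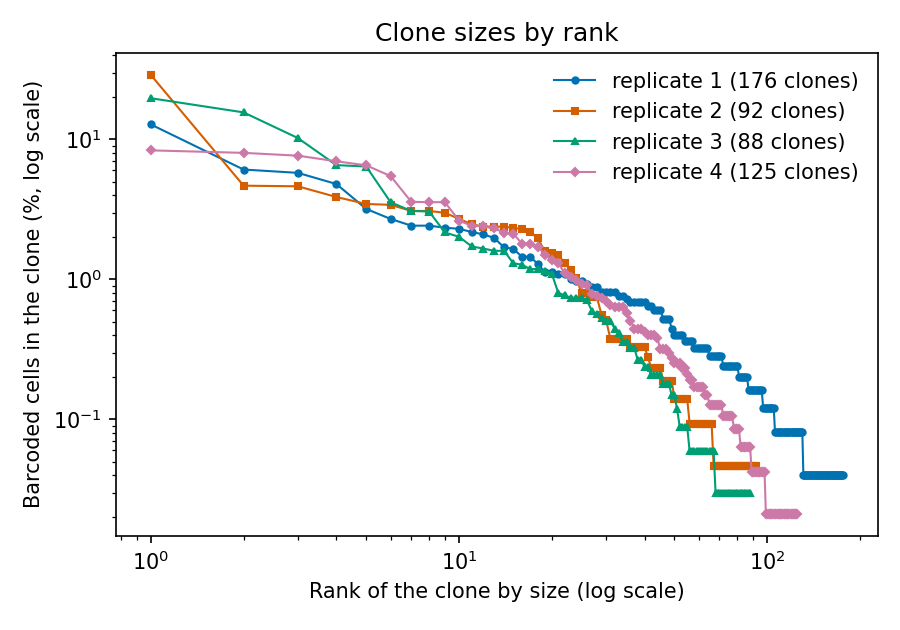
Each point is a clone, with its rank by size on the horizontal axis and its percent of the replicate's barcoded cells on the vertical axis, both on log scales, and each colour is a replicate. The top clone ranges from 8.35% in replicate 4 to 28.9% in replicate 2, and every curve ends in a flat run of clones seen in 1 cell.

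The 3 largest clones of each replicate carried different barcodes, and each was labelled c2, c3 or c4 by the authors. In replicate 1 the clone GTGATATTTTGCCGATGGTCT had 317 cells and the label c4, followed by GTGGTTTCAAACAGTTTGGGG with 151 cells and c2, and by GTGTTTGTTCTTCAAATTTGT with 143 cells and c3. In replicate 2 the clone GTGTCCCTGGTGTTTGCGCCA had 618 cells and the label c3. The next clones there, GTGGGTTCTGAGGGTCTGAAT (c3) and GTGGTGGTACTAGTGGTTTCC (c4), had 100 and 99 cells, with overlapping intervals of 3.82% to 5.65% and 3.77% to 5.60%. Replicate 3 was led by GTGTTTCTCATTGACTGTTAT (c3, 664 cells), GTGCCGAGGAGGCATAGATTG (c4, 526 cells) and GTGGGGGCCGCGGCTTATGTC (c4, 345 cells), which together held 45.5% of its barcoded cells. Replicate 4 was led by GTGATGTTGTCAGGTAGCTGC (c3, 394 cells), GTGGGTCCGGGGGCGCTGTTT (c4, 378 cells) and GTGCCTTCTCGGTTGTTTTTT (c3, 361 cells). The intervals of these 3 shares overlapped, at 7.58% to 9.18%, 7.25% to 8.82% and 6.91% to 8.45%.

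Clone sizes were far from equal in each replicate. The effective number of clones, which is the number of equally large clones that would give the same Simpson index, was 29.0 ± 1.29 in replicate 1 and 24.3 ± 0.521 in replicate 4 (bootstrap SE over cells). It was 9.91 ± 0.503 in replicate 2 and 11.3 ± 0.320 in replicate 3. The mean was 18.6 ± 9.46 (SD, n = 4). Shannon evenness, which is 1 for equal clones, was 0.796, 0.709, 0.685 and 0.759. Against equal clone sizes, the chi-square was 71.9, 195, 263 and 158 times its degrees of freedom, with an adjusted p of 1e-05 in each of the 4 replicates, the smallest that 100000 Monte Carlo draws can give (upper tail, Benjamini-Hochberg over the replicates). This test treats the cells of a library as its units.

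Small clones were numerous and held few cells. Clones seen in 1 cell numbered 46, 26, 21 and 27, which is 26.1% (19.8% to 33.3%), 28.3% (19.4% to 38.6%), 23.9% (15.4% to 34.1%) and 21.6% (14.7% to 29.8%) of the clones. Their mean share of the clones was 24.97% ± 2.87 (SD, n = 4), and their share of the barcoded cells was 1.86%, 1.21%, 0.622% and 0.572%. The 53, 30, 37 and 55 clones of at least 10 cells held 84.3%, 91.5%, 95.5% and 95.2% of the cells. The Chao1 estimate was 216, 119, 104 and 157 clones. It is a lower bound on the number of clones, computed from the clones of 1 and of 2 cells. In replicate 1, 11 of the 46 clones of 1 cell had no label and lay within 2 bases of a larger clone. With barcodes up to 2 bases apart merged, an alternative for Chao1 added after the data had been seen, replicate 1 had 34 clones of 1 cell (20.7%) and a Chao1 estimate of 186. Counting only clones of at least 3 cells lowered the mean to 75.75 clones per replicate.

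Nearly all barcodes were found in a single replicate. Of 475 distinct barcodes, 6 were in more than 1 replicate and 0 in 3 or more, and each of the 6 was in replicate 2. Replicate 2 shared 1 barcode with replicate 1, 3 with replicate 3 and 2 with replicate 4, and the other pairs shared 0. The barcode GTGTTTTTTTGTTTGTTTGCT was a sizeable clone in both its replicates, with 64 cells in replicate 2 and 60 in replicate 1, labelled c3 in both. GTGGGTTCTGAGGGTCTGAAT had 100 cells in replicate 2 and 1 cell in replicate 4, and GTGAGATTCGCTTCAACTCGA had 58 cells in replicate 2 and 1 cell in replicate 3. GTGATTGCGTTTTCTGGCAAT and GTGTATTGCTTTGCTTATTTT had 2 cells in replicate 2 and 1 cell in replicates 4 and 3. The last one, GTGCGGATGCCCGCCGGTGTT, lies outside the naming rule and had 1 cell in replicate 2 and 1 cell in replicate 3. The number of matches expected if the barcodes were drawn at random with the observed base composition was 3.89e-05 over all 6 pairs of replicates, and 0.00242 when it was computed among barcodes with the same number of T. Among clones of at least 2 cells, 1 barcode was shared.

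The authors' tables gave each clone 1 of 4 labels, c1 to c4, the same in all its cells within a replicate. The header over them reads Cluster, but what was clustered, how the labels were made and what they stand for is not given in the sources used here. Nor is it given whether a label means the same in each replicate, which the comparisons over replicates assume. The comparisons by label were chosen after the clone sizes per label had been seen. Clones labelled c3 and c4 held most of the labelled cells, 46.6% ± 16.4 and 35.4% ± 19.5 of the cells of labelled clones (SD, n = 4). Clones labelled c2 held 12.6% ± 6.40 and clones labelled c1 5.46% ± 3.004. Together c3 and c4 held 73.5%, 82.9%, 90.5% and 81.0% of the cells of labelled clones in replicates 1 to 4, which leaves out cells without a barcode or label, a mean of 82.0% ± 7.005. Of the labelled clones, 29.7% ± 12.5 were c3, 31.2% ± 11.1 c4, 20.5% ± 7.87 c2 and 18.7% ± 9.81 c1. For c3 the share of cells exceeded the share of clones in 4 of 4 replicates, by 39.2% against 38.7% in replicate 1 at the least. That gap is within the interval of the share of clones (31.1% to 46.6%). In replicate 3 the excess rested on the clone of 664 cells. Without it c3 held 9.48% of the cells, against 14.8% of the clones with it counted. For c4 the share of cells was lower in replicate 2 (27.2% of clones, 19.9% of cells) and level at 24.0% in replicate 4.

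The label make-up differed between replicates by more than the error of sampling clones. In replicate 3, 42 of the 88 clones were labelled c4, or 47.7% (37.0% to 58.6%), and 13 were labelled c3, or 14.8% (8.11% to 23.9%). In replicate 2 the share of c3 was 41.3% (31.1% to 52.1%) and that of c1 5.43% (1.79% to 12.2%). Over all 468 labelled clones the labels were unevenly spread over the replicates, with Cramer's V of 0.191 and p = 1e-05, the smallest that 100000 permutations can give. This test treats clones as units and covers only the error of sampling clones. It also takes each label to mean the same in all replicates, which the sources do not state. The largest clones weighed heavily on the shares of cells. When the largest clone of the replicate was left out, c3 went from 62.9% to 47.9% of the cells of labelled clones in replicate 2 and from 27.3% to 9.48% in replicate 3. Likewise c4 went from 34.3% to 24.6% in replicate 1 and from 63.2% to 78.7% in replicate 3.

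**Figure D2:**
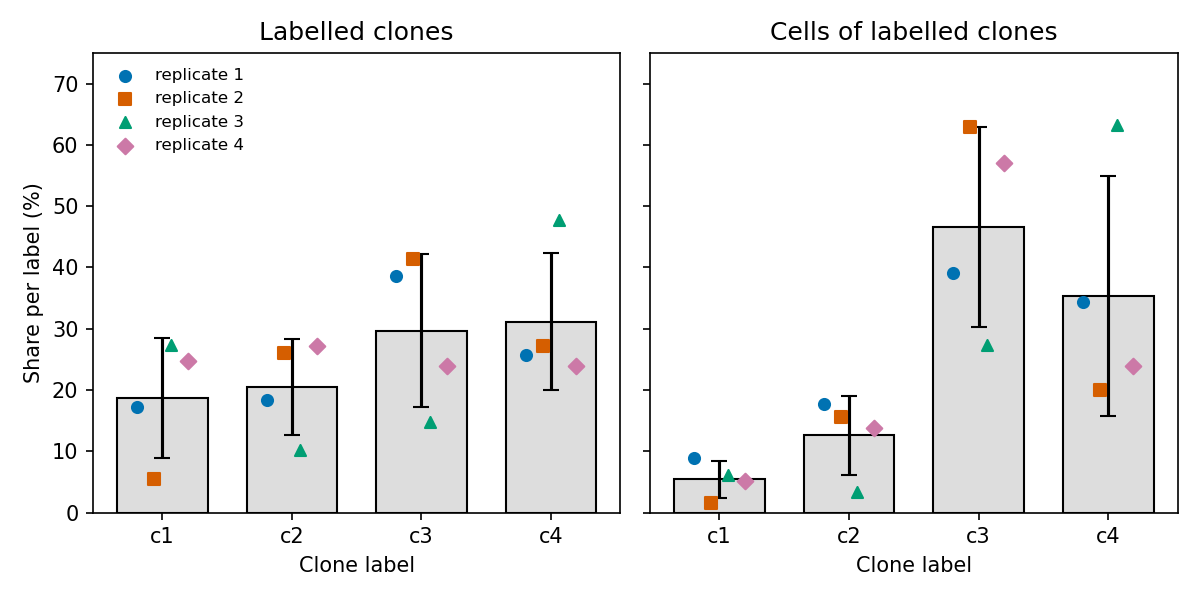
Grey bars give the mean over the 4 replicates of each label's percent of labelled clones (left) and percent of their cells (right), error bars the SD, and points the replicates. Clones labelled c1 make up 18.7% of clones and 5.46% of cells, and those labelled c3 29.7% of clones and 46.6% of cells.

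Clones labelled c3 or c4 were larger than clones labelled c1. The geometric mean size of c1 clones was 3.73, 2.57, 3.88 and 3.01 cells in replicates 1 to 4. It was 7.10, 6.97, 10.7 and 26.3 cells for c3, and 5.34, 5.92, 10.7 and 10.7 cells for c4. Averaged over replicates, c3 clones exceeded c1 clones by 1.74 ± 0.96 on the log2 scale (SD, n = 4), a 3.34-fold difference that was higher in 4 of 4 replicates (permutation test, adjusted p = 0.00012). Clones labelled c4 exceeded c1 clones by 1.25 ± 0.55, or 2.38-fold, in 4 of 4 replicates (permutation test, adjusted p = 0.00096). Clones labelled c3 exceeded c2 clones by 0.97 ± 0.62, or 1.96-fold, in 4 of 4 replicates (permutation test, adjusted p = 0.0149). The remaining pairs did not pass the threshold of 0.05 by the permutation test. The difference of c2 over c1 was 0.77 ± 0.41 (adjusted p = 0.0548 by permutation) and that of c4 over c2 0.49 ± 0.36 (adjusted p = 0.156 by permutation), both also above 0 in 4 of 4 replicates. That of c4 over c3 was -0.49 ± 0.57 (adjusted p = 0.156 by permutation) and above 0 in 1 of 4 replicates, and -0.21 without replicate 4.

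These tests were two-sided, with labels permuted among the clones of a replicate and Benjamini-Hochberg adjustment over the 6 pairs, so they treat clones as units. With the 4 replicates as units, an exact sign-flip test cannot give a p below 0.125, a value that each pair but c4 against c3 reached. Over all labels the permutation test gave a summed Kruskal-Wallis H of 36.3 and p = 0.00019. Taken singly, replicate 4 passed the threshold (permutation test, adjusted p = 0.0002) and replicates 1 to 3 did not (0.212, 0.560 and 0.212), and without replicate 4 H was 12.8 and p 0.167. Its c3 clones were 8.76-fold larger than its c1 clones, against 1.90-fold, 2.71-fold and 2.75-fold in replicates 1 to 3. On the log2 scale these differences were 3.13 against 0.93, 1.44 and 1.46. On that scale replicate 4 did not stand apart from the others by Dixon's test (ratio of gap to range 0.758), and the folds themselves were not tested. Replicate 4 did stand apart by that test in the median size of its c3 clones, at 31.5 cells against 8 or fewer in the other replicates (ratio 0.870). Among clones of at least 3 cells the differences of c3 and c4 over c1 were 0.91 and 0.55 and did not pass (permutation test, adjusted p = 0.325 and 0.362). The only c1 clone of that size in replicate 2 had 28 cells, and each replicate weighs equally in these means. The difference of c3 over c2 did not pass with clones of at least 2 cells or 3 cells, without the 3 largest clones of each replicate, or without replicate 4 (permutation tests, adjusted p = 0.0510, 0.272, 0.0534 and 0.249).

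**Figure D3:**
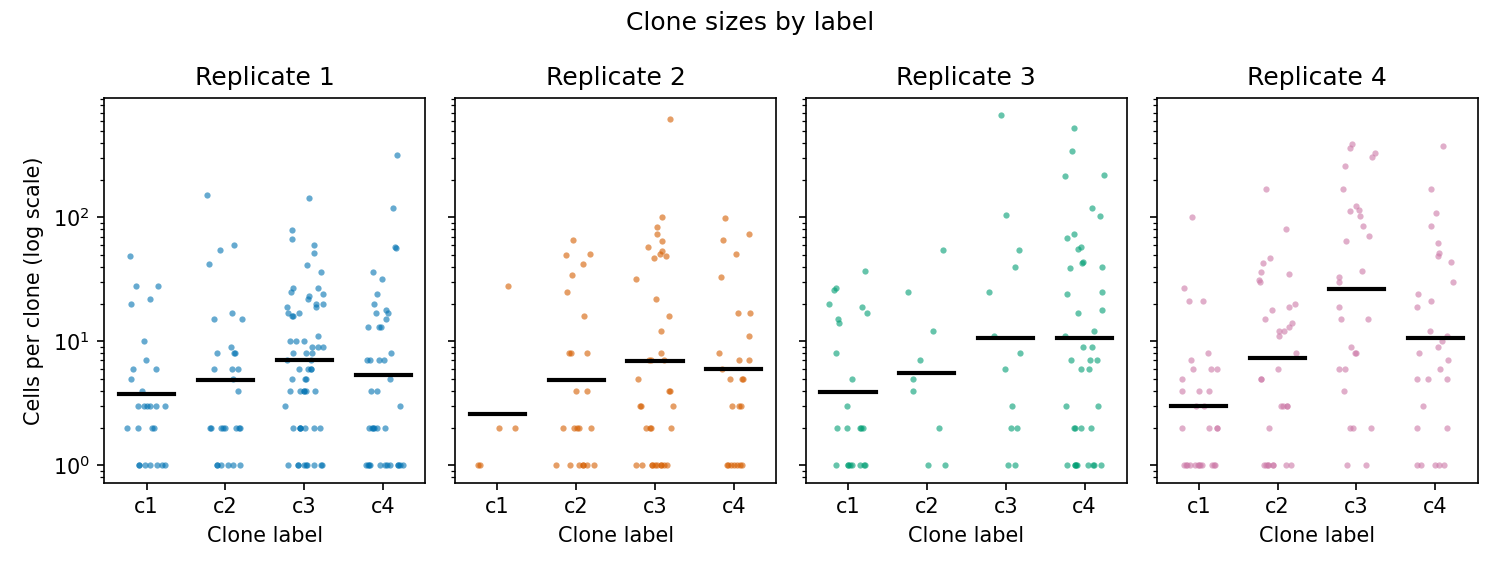
Each point is a clone, with its number of cells on a log axis, by label and replicate, and the black line is the geometric mean. The lines for c3 stand at 7.10, 6.97, 10.7 and 26.3 cells and those for c1 at 3.73, 2.57, 3.88 and 3.01 cells in replicates 1 to 4.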

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

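The test of the barcodes without a label was chosen after they had been seen. In 3 of 38 measures compared over the 4 replicates, a replicate stood apart from the others by Dixon's test, and chance does so in about 1 of 20 such measures. The share of clones labelled c4 was 47.7% in replicate 3, against 25.8%, 27.2% and 24.0% in replicates 1, 2 and 4. The median c3 clone had 31.5 cells in replicate 4, against 7, 4.5 and 8 cells in replicates 1, 2 and 3. The median c1 clone had 3 cells in replicate 1 and 2 cells in the other replicates, whose tie makes any difference stand apart, so this case carries no information.

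Outside the comparisons by label, 15 cells of replicate 1 carried a DNA barcode without a label, and 4 cells of replicate 1 carried a barcode that did not start with GTG. The other replicates had 0 of either kind. The 15 cells held 13 barcodes, 12 of them seen in 1 cell and the largest in 3 cells. Of the 13 barcodes, 11 were within 2 bases of a larger clone of the replicate, against 1 of 34 labelled 1-cell clones there (two-sided Fisher's exact test, p = 5.1e-08), which is consistent with sequence errors in the barcodes of larger clones. The other 2 barcodes hold the 4 cells without GTG, and 0 of these 2 were within 2 bases of a larger clone. Among labelled clones of any size, 1 of 163, 0 of 92, 2 of 88 and 0 of 125 in replicates 1 to 4 lay within 2 bases of a larger one. Barcodes close to a larger clone were thus also found in replicate 3, with a label. What produced the 2 barcodes without GTG, and whether the authors left unlabelled barcodes in replicate 1 alone or the other libraries had none, stays open, and no biological explanation was tested.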

How the results depend on the processing

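All alternatives for the comparisons by label were chosen after the data had been seen, and those for the clone measures were planned, except the Chao1 estimate with merged barcodes. Of 170 values recomputed, 157 kept their direction and side of the threshold or moved by less than the spread between replicates. Direction changed in 0. The number of shared barcodes was judged by its ratio to the main count instead. Part of the 157 was fixed in advance, so this count is no measure of robustness. Leaving out 1 of 4 replicates cannot move a mean by as much as the SD over replicates. The share of cells with several barcodes is 0 by layout, and merging barcodes keeps all barcoded cells. With at least 2 cells per clone, a mean of 90.25 clones still counted as kept. The number of clones fell to 75.75 per replicate with at least 3 cells per clone, by construction. The shared barcodes fell from 6 to 1 with at least 2 or at least 3 cells per clone, since 5 of the 6 had 1 cell in a replicate, and leaving out a replicate gave 0 (without replicate 2) to 5, with 3 without replicate 3. Leaving out a replicate gave an overall H of clone size by label of 12.8 (without replicate 4, p = 0.167 by permutation) to 34.2. The difference of c3 over c1 ranged from 0.91 to 2.01 on the log2 scale and passed the threshold in 11 of 12 log2 alternatives, the exception being clones of at least 3 cells (adjusted p 6e-05 to 0.325), where c4 over c1 was lost too. With that minimum the only c1 clone left in replicate 2 had 28 cells. The difference of c3 over c2 was lost with clones of at least 2 cells (0.81) or 3 cells (0.72), without the 3 largest clones of each replicate (0.74) and without replicate 4 (0.68), and c2 over c1 passed with unlogged sizes (7.17 cells). The causes were not tested. Not run were a minimum of reads per barcode, other treatments of cells with several barcodes, and tests of a state or number per cell, since the tables hold none of these. No paired analysis was possible because the transcriptome libraries, which share the replicate numbers, have no values analysed here. Depth limits small clones: at 2141 to 4718 cells, clones seen in 1 cell cannot be ordered by size.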

Other observations

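The tests of c1 among large clones, the labels of doubtful 1-cell clones and the tests of shared barcodes were chosen after the results had been seen. The very large clones were mostly labelled c3 or c4. Of 63 clones of 50 or more cells, 29 were c3, 24 c4, 9 c2 and 1 c1. At the other end of the range, 33.0% of the 88 c1 clones were seen in 1 cell, against 23.7% of the 97 c2 clones, 15.97% of the 144 c3 clones and 23.7% of the 139 c4 clones. These shares pool the replicates and were not tested, and in replicate 1 the share was higher for c4 (28.6%) than for c1 (25%).

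The random part of the barcodes was rich in T, with 44.0% T, 23.0% G, 17.9% C and 15.1% A over the 475 distinct barcodes, and between 38.7% and 50.5% T at each position. The hypothesis that clone size follows the T content of the barcode was tested across clones, which are not independent replicates. Spearman's rho was 0.0392 ± 0.0262 (SD over 4 replicates), with p = 0.410 by a two-sided permutation test, and within 0.1 of 0 in each replicate.

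Clones labelled c1 were smaller than clones labelled c3, by 1.74 ± 0.96 on the log2 scale. Barcodes misread or carried over from another replicate, and the 3 largest clones of each replicate, are argued against as the whole cause. Without such barcodes the difference was 1.64 (permutation test, unadjusted p = 5e-05). Without the 3 largest clones of each replicate it was 1.46 (permutation test, unadjusted p = 7e-05). Other large clones stayed in, as replicate 4 alone had 13 c3 clones of 50 or more cells. Whether 1-cell clones had simply been given the label c1 was tested among clones of at least 3 cells, which keeps 302 of 468 clones and 44 of 88 c1 clones: the difference was then 0.91 ± 1.26 (permutation test, p = 0.108), smaller and with a wider spread, which decides nothing. In replicate 2 that difference rests on the only c1 clone of that size there, which had 28 cells. Among the 63 clones of 50 or more cells 1 was c1, against 8.79 expected from the clones of at least 3 cells (one-sided permutation test within replicates, p = 0.00032). This count was tested after it had been seen and after the result for clones of at least 3 cells. With every minimum size tried and that choice allowed for, the permutation p was 0.00070. The choice of the label c1 and of the side tested was not allowed for. Within that limit, this argues against 1-cell clones having been given c1 as the cause only for the lack of large c1 clones. Of the 108 labelled 1-cell clones, 29 were c1, which argues against the label c1 having been given to every 1-cell clone. It does not decide whether such clones were given c1 more often than larger ones. For the rest of the pattern that weaker form, how the authors made the labels and whether clone size entered into them stay open, as no group in the design gives a biological explanation to test.

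The 6 barcodes found in more than 1 replicate all involved replicate 2, and 5 of them had 1 cell in a replicate. A chance match of independently drawn barcodes is argued against by the 3.89e-05 matches expected at the observed base composition. That value takes all barcodes to share 1 composition and understates chance. The shared barcode with 64 and 60 cells was rich in T (77.8% of its random part), but among barcodes with the same number of T 0.00242 matches were expected. Between replicates, 0 pairs of barcodes were 1 or 2 bases apart and 8 were 3 bases apart, against 6 identical ones. The number expected 3 bases apart was not computed. For 0 of the 5 barcodes with a single copy were its cell barcode and DNA barcode listed together in the other replicate, which argues against exchanged reads of such listed cells as the cause of most copies, but for 1 of the 5, GTGAGATTCGCTTCAACTCGA, the cell barcode of the copy in replicate 3 was listed in replicate 2 under another DNA barcode (chance of at least 1 such case 0.0030), so reads exchanged from a cell listed under another DNA barcode stay open. Barcodes that were frequent in the virus pool, descendants of 1 transduced cell in different recipients, and cells carried over in handling stay open and were not tested.

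Of the 6 shared barcodes, 1 had the same label in both replicates, and in 4 the copy of 1 cell outside replicate 2 was labelled c1 and the copy in replicate 2 c3. Some 1-cell clones of replicates 3 and 4 were close to a larger clone or shared with another replicate. Of these, 5 of 6 were c1, against 15 of 42 other 1-cell clones there (two-sided Fisher's exact test, p = 0.0692). Replicates 1 and 2 were left out of this test. Labelled 1-cell clones of this kind were c2 in replicate 1 and c3 in replicate 2, not c1. Cell barcodes were also shared: 16 occurred in a pair of replicates, and 0 of them with the same DNA barcode. If cell barcodes were drawn evenly and none were removed, this corresponds to a pool of 4.74e+06 cell barcodes (95% Poisson interval 2.92e+06 to 8.29e+06). From general knowledge of the kits, that is more than the v2 list holds, so the kit version named in the labels is in doubt, and no other value given here depends on it.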
